A study of Arabidopsis thaliana with 12 samples.

How the data were processed

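RNA abundance was measured on 12 arrays of Arabidopsis thaliana, 6 from the flu mutant and 6 from wild type (WT), both of the Landsberg ecotype per the labels. All plants were harvested 30 min after return to light, following 12 h of darkness. FLU is a nuclear-encoded plastid protein that restrains chlorophyll synthesis in the dark. A flu plant therefore accumulates the chlorophyll precursor protochlorophyllide at night, and this pigment releases singlet oxygen when light returns. Whether the 6 arrays of a group came from separate plants is not given in the sources used here, so the p-values measure only the spread between these arrays, which may be technical.

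The values used are those in the deposited series table, which holds 1 intensity on a linear scale for each of 3439 probes and 12 arrays. Scanner, background correction and scaling of these deposited intensities are not given in the sources used here. The values run from 0 to 100, and each array has between 1 and 3 probes at the highest value and between 108 and 165 at 0. The array sums lie between 3247 and 3350 and the array medians between 0.426 and 0.491. The number of arrays, and not a count of molecules, limits the precision.

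The rule fixed before the data were examined took the table as normalised only if the medians or 2% trimmed means agreed within 5%. The medians spread by 15.4% and the trimmed means by 11.6%, so the arrays were quantile normalised. The flu medians, 0.426 to 0.442, all lay under the WT medians, 0.443 to 0.491. Quantile normalisation therefore also removed a difference in level between the groups, and whether that difference is technical cannot be told. Values under the 25th percentile of all values, 0.250, were raised to that floor, and log2 was taken. The 311 probes at the floor on all 12 arrays were not tested, which left 3128. The floor compresses differences of dim probes, and a fold against a group wholly at the floor is given as a lower bound.

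The arrays were compared before any test. Within a group, arrays 1 and 2, 3 and 4, and 5 and 6 resembled each other more than any other arrays: the correlation of their deviations from the group mean was 0.21 to 0.68, against -0.55 to -0.04 for other pairs of the same group. All 12 arrays were closest to that partner. Their log2 values correlated at 0.947 to 0.980. Each such pair may be a repeat of 1 sample, so its mean was used as 1 replicate, giving 3 pair means per group. This departs from the plan, which took the 12 arrays as separate; that fit called 1732 probes where the fit of the pair means called 1216, with 1215 in common. The choice was made from the correlations, before the calls were compared. Arrays with the same number in the 2 groups also deviated together, with correlations of 0.23 to 0.46 for the arrays and 0.46, 0.38 and 0.26 for the pair means, so the numbers pair the samples. This pairing comes from the data, not from a label. The main fit holds the group only, as planned, so its errors and p-values leave this pairing out. The fit with the pair as a block is an alternative, and it called 1371 probes.

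Pair means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, Benjamini-Hochberg adjustment over the tested probes, threshold 0.05). Every adjusted p per gene comes from limma, and errors are standard errors (SE) of log2 differences or SDs over the 3 pair means. Gene lists with at least 3 measured genes were tested with camera at its preset correlation, with an estimated correlation and fry as alternatives.

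Probes were named through the GEO platform annotation, which can be old, with symbols updated through the TAIR10.1 gene table. Of the 3439 probes, 692 have 1 gene, 870 have several and 1877 are not listed there and stay unnamed. Of the 692, 690 matched the gene table. No gene was named from a probe with several genes. The build behind the probes is not given in the sources used here, so no coordinates are printed. The platform annotation lists 0 probes for FLU, so the labels were not checked on its transcript.

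The genes named were chosen by a rule fixed before the data were examined. It takes, among genes with a probe of their own and past the threshold, the 12 with the largest log2 difference in each direction, and in each list the 3 members with the smallest p. Where a gene had more than 1 probe, the brighter was used. For AT2G25870 the probes disagreed: one gave a log2 difference of -0.57 (limma adjusted p = 0.090) and the other 0.75 (limma adjusted p = 0.012).

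Of the 24 lists fixed beforehand, 23 named 393 genes by locus, of which only 8 had a probe of their own that was tested. Lists of stress factors, hormones, heat shock proteins, antioxidant enzymes, clock, touch, cold, sugar starvation, housekeeping and organ or cell type markers, 20 in all, had 0 tested genes, and their members are not analysed here. The list of ribosomal proteins was defined by annotation words, which found 2 genes in the gene table and 0 tested ones, so its coverage was not settled. A further 11 lists were drawn up from the names of measured genes, after the probe table was seen and before any difference was.

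The log2 differences turned out to depend on probe number with a period of 288, the lag at which these same differences correlated most. An alternative therefore removed, from each array, the median deviation by probe number modulo 6 and within a window of 7 numbers modulo 288. This correction and its tests were chosen after seeing the data. The other alternatives changed the floor, the filter on dim probes, the normalisation, the block, the weights, the variance prior and the arrays included.

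The fit was tested on simulated data with the pair structure of these arrays, 3128 probes and 5 simulations. With no change, the pair means gave 0 false calls and the 12 separate arrays gave 36.8 on average. With 200 probes changed by a log2 of 1, the pair means recovered 64.0% with 5.4 false calls. At a log2 of 2 they recovered 94.0% with 10.4 false calls. When the observed position effect was added to the log2 of 1 simulation, the uncorrected fit made 682.6 false calls on average and the corrected one 7.4, with 76.3% and 60.8% of the changed probes recovered.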

Results

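The series compared transcript levels of the flu mutant with wild type shortly after return to light, when the mutant meets light with excess protochlorophyllide. The question is which genes differ in expression at that time. All 12 arrays are from that time, so rose and fell mean higher and lower in flu than in WT, not a change over time. Whether a difference was there before the light cannot be told. Each of the 12 arrays gave 3439 intensities, and the 6 arrays per group were reduced to 3 pair means. Log2 values correlated at 0.928 to 0.980 within flu, 0.842 to 0.974 within WT and 0.646 to 0.784 between the groups. The first principal component took 61.7% of the variance and separated flu from WT.

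**Figure D1:**
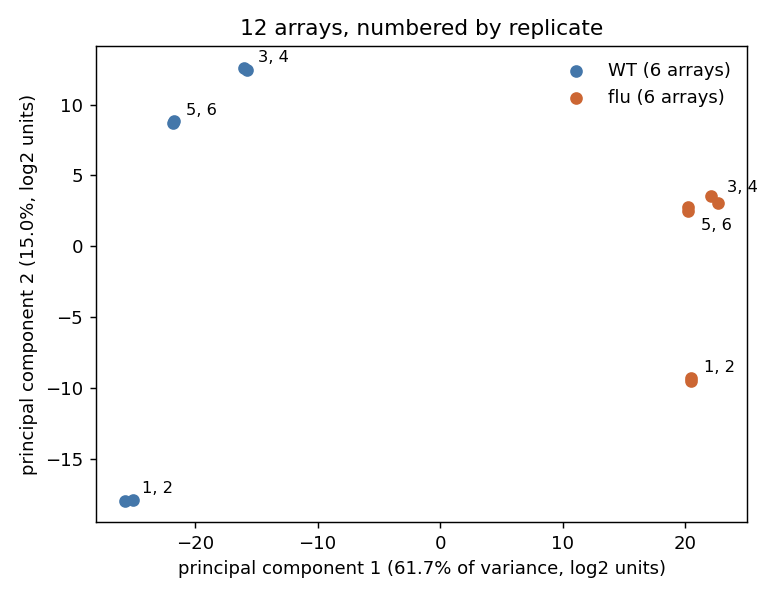
Principal components 1 and 2 of the log2 intensities of 12 arrays, with each point 1 array and the replicate numbers beside it. Arrays 1 and 2, 3 and 4, and 5 and 6 of a group lie together, and component 1, with 61.7% of the variance, parts WT from flu.

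Probe intensities of many genes differed between flu and WT, and how far this reflects their transcripts is weighed in the last section. AT4G35660, a gene without a symbol in the gene table, rose most, 24.9-fold, and AT3G23940, a dihydroxy-acid dehydratase of branched-chain amino acid synthesis, rose 5.85-fold. AT3G52960, a plastid peroxiredoxin, rose 4.04-fold. AT1G03810 fell most, with WT 5.06-fold above flu, followed at a distance by AT1G02020, 2.80-fold, and LpxA, an enzyme of lipid A-type synthesis, 2.74-fold. GLDH, which catalyses the last step of ascorbate synthesis, was 2.48-fold lower in flu. These folds are not corrected for the dependence on probe number given below. Some also depend on the floor. In WT, AT4G35660 and AT3G52960 were above it on 4 of 6 arrays and AT3G23940 on 5, and in flu AT1G02020 was above it on 5.

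By limma, 1216 of 3128 probes passed the threshold, 547 higher and 669 lower in flu, and 537 of them differed by at least 2-fold (287 higher, 250 lower). Among the 620 genes with a probe of their own, 228 passed, 105 higher and 123 lower. The pair means of flu and WT did not overlap for 1581 probes (50.5%), where chance gives 10% for 3 against 3 independent values. The pairing by number and the shared dependence on probe number depart from that, so the 10% is only a guide. Differences depended on where a probe stood in the numbering: with that position effect removed, 1131 probes passed, 597 higher and 534 lower, and 792 of the 1216 passed in the same direction. Probes at least 2-fold different then numbered 353.

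**Figure D2:**
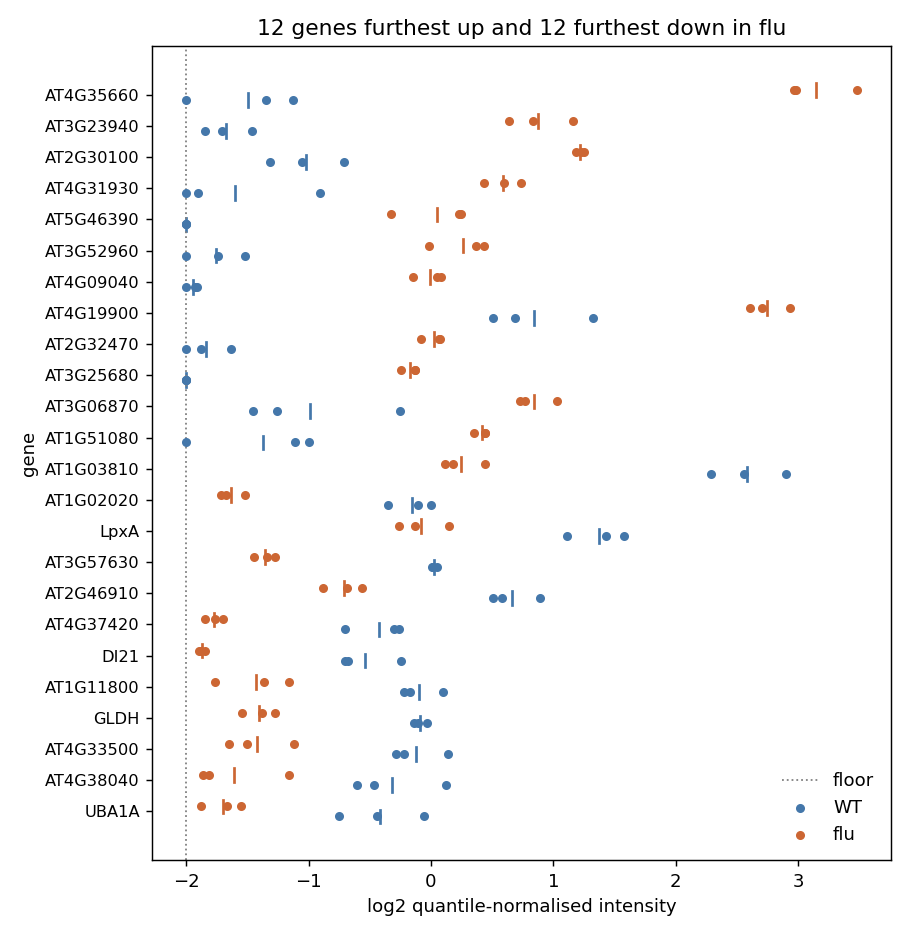
Log2 quantile-normalised intensity of the 12 genes with the largest rise and the 12 with the largest fall in flu, with each point 1 pair mean (3 per group) and each bar the group mean. The groups do not overlap for any of the 24 genes, and 2 genes, AT5G46390 and AT3G25680, have all WT values at the floor, the dotted line.

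All 12 genes with the largest rise, and all 12 with the largest fall, also passed with the position effect removed and with the replicate block. The intensity of AT4G35660 was 8.98 ± 1.91 in flu and 0.367 ± 0.106 in WT (SD, n = 3 pair means). Its log2 difference was 4.64 (SE 0.27, limma adjusted p = 0.00051), and 4.34 with the position effect removed. AT3G23940 stood at 1.86 ± 0.345 in flu and 0.316 ± 0.043 in WT, a log2 difference of 2.55 (SE 0.18), and of 1.90 with the position effect removed. AT3G52960 stood at 1.21 ± 0.194 in flu and 0.299 ± 0.050 in WT, a log2 difference of 2.02 (SE 0.18, limma adjusted p = 0.00094), and of 1.62 with the position effect removed. AT5G46390, of the family of C-terminal processing peptidases, was at the floor on all 6 WT arrays and at 1.05 ± 0.219 in flu, so it was at least 4.14-fold higher. AT3G25680 was likewise at the floor in WT and at least 3.56-fold higher in flu. For these 2 the position correction acts on floored values in all of WT. It acts on some floored WT values in others too. AT3G23940 was above the floor on 5 of 6 WT arrays, AT4G35660, AT3G52960 and AT1G51080 on 4, AT4G31930 on 3, and AT4G09040 and AT2G32470 on 2. AT4G19900 stood at 6.74 ± 0.797 in flu and 1.85 ± 0.575 in WT, a log2 difference of 1.91, and of 2.26 with the position effect removed. The other 6 that rose most, AT2G30100, AT4G31930, AT4G09040, AT2G32470, AT3G06870 and AT1G51080, had log2 differences from 1.79 to 2.25.

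AT1G03810 stood at 1.19 ± 0.145 in flu and 6.08 ± 1.30 in WT, a log2 difference of -2.34 (SE 0.19, limma adjusted p = 0.00074) and of -1.73 with the position effect removed. LpxA stood at 0.951 ± 0.139 in flu and 2.62 ± 0.418 in WT, a log2 difference of -1.46, and of -1.05 with the position effect removed. GLDH stood at 0.379 ± 0.035 in flu and 0.938 ± 0.036 in WT, a log2 difference of -1.31 (SE 0.11) and of -1.02 with the position effect removed. AT2G46910, a fibrillin-type plastid protein, had a log2 difference of -1.37 (SE 0.15), and of -0.92 with the position effect removed. DI21, named for induction by drought, fell by 1.33 on the log2 scale, and AT4G33500, of the PP2C phosphatase family, fell by 1.30. With the position effect removed they fell by 0.91 and 1.25. DI21 was above the floor on 3 of the 6 flu arrays, so the size of its fall depends on the floor. The remaining 6 were AT1G02020, AT3G57630, AT4G37420, AT1G11800, AT4G38040 and UBA1A, with log2 differences from -1.48 to -1.29; AT1G11800, at -1.33, stood at -0.78 with the position effect removed. AT1G02020, AT4G38040 and UBA1A were above the floor on 5 of the 6 flu arrays. AT4G38040 did not pass without flu arrays 3 and 4 or without flu arrays 5 and 6 (limma adjusted p = 0.053 and 0.052).

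Photosystem and carbon fixation genes, the only list fixed beforehand with enough measured members, showed no change that passed. Of its 5 measured genes, 0 passed over all genes and 0 adjusted over the list alone, and camera gave an adjusted p of 0.98. The list median was 0.05, with a mean of -0.06, and the median was 0.45 with the position effect removed, where fry gave an adjusted p of 0.010 and camera 0.46. The photosystem II subunit gene PSBW stood at 18.5 ± 1.07 in flu and 18.0 ± 2.20 in WT. PSBW, SBPASE and PSBY had log2 differences of 0.05, 0.29 and 0.16, and with the position effect removed these 3 of the 5 passed, at 0.45, 0.64 and 0.64 (limma adjusted p = 0.038, 0.020 and 0.048). PRK, phosphoribulokinase of the Calvin cycle, had a log2 difference of -0.73 (limma adjusted p = 0.109); it passed with the replicate block (0.021), and with the position effect removed it stood at -0.34 (0.409). The antenna gene LHB1B2 stood at 16.4 ± 1.61 in flu and 19.7 ± 2.87 in WT (log2 difference -0.26, limma adjusted p = 0.216), and at 0.14 with the position effect removed. The tetrapyrrole list had 2 measured genes and neither passed, also adjusted over the list alone: AT1G74470, the geranylgeranyl reductase of chlorophyll synthesis, had a log2 difference of 0.32 (SE 0.22), and CHLM, the magnesium-protoporphyrin methyltransferase, -0.12 (SE 0.22). With the position effect removed they stood at 0.58 and 0.48 and did not pass.

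The other lists were drawn up from the measured genes' names. By camera, 0 of all 12 lists passed, at the preset or at an estimated correlation. At the preset correlation 2 had an unadjusted camera p under 0.05, cell wall enzymes (0.019) and redox genes (0.043). At the estimated correlation these were 0.098 and 0.106. By fry, which asks whether a list's members move one way, 4 passed: NDH complex genes upward, and redox, cell wall and stress-named genes downward. Unlike camera, fry does not set a list against the other genes. As 228 of all 620 genes passed, a list can pass fry, or hold several genes that passed, without standing out. With the position effect removed 0 passed by camera and 6 by fry: NDH complex, cell wall and stress-named genes again, not redox genes, and newly the photosystem and carbon fixation genes upward (adjusted p = 0.010) and the nuclear transcription (0.0042) and plastid chaperone genes (0.032) downward. The cell wall median was then -0.09, against -0.62. The median, mean and camera direction differed in sign for carbon metabolism (median -0.54, mean -0.04, upward) and calcium-related genes (median -0.03, mean 0.06, upward).

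Of 4 genes for the chloroplast NDH complex, which carries electrons around photosystem I, 1 rose. CRR41, needed for assembly of the complex, had a log2 difference of 1.39 (SE 0.13, limma adjusted p = 0.0010) and passed with the position effect removed. CRR21 and the subunit NdhS had log2 differences of 0.74 and 0.90 that did not pass (limma adjusted p = 0.124 and 0.150). Their median was 0.82 (fry adjusted p = 0.033; camera adjusted p = 0.26, or 0.78 with an estimated correlation).

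Of 6 redox and antioxidant genes, 3 fell: GLDH, SRX and NTRC. Adjusted over the list alone 4 passed, these and CHL (-0.46, limma adjusted p over all genes 0.072), picked after its values were seen. SRX, which restores overoxidised peroxiredoxins, fell by 0.60 on the log2 scale, and NTRC, which passes electrons from NADPH to plastid peroxiredoxins, fell by 0.73. With the position effect removed GLDH passed, and SRX and NTRC did not, at -0.32 and -0.19 (limma adjusted p = 0.272 and 0.527). SRX and NTRC also did not pass with any flu pair of arrays left out, or without WT arrays 3 and 4 or 5 and 6 (limma adjusted p from 0.055 to 0.080 and from 0.058 to 0.090). The list was drawn from gene symbols and does not hold AT3G52960, the plastid peroxiredoxin that rose 4.04-fold. The list gave a fry adjusted p of 0.0026, and of 0.063 with the position effect removed; camera gave 0.26, or 0.64 with an estimated correlation.

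Of 5 cell wall enzyme genes, 3 fell. GH9B16 and GH9B11, of the endoglucanase family, were 2.11-fold and 2.14-fold lower in flu, and both passed with the position effect removed, GH9B11 at -0.70. CSLA01, of the mannan synthase family, fell by 0.62, and with the position effect removed it stood at -0.09 (limma adjusted p = 0.675); it also did not pass without flu arrays 1 and 2 or 3 and 4 (0.069 and 0.075). Of 7 stress-named genes 3 fell, DI21, RALFL32 and DRT101. RALFL32, a gene for a small signalling peptide, fell by 1.17 and DRT101 fell by 0.93 on the log2 scale. All 3 passed with the position effect removed, RALFL32 at -0.62 and DRT101 at -0.49. Adjusted over the list alone 6 of the 7 passed, 4 lower and 2 higher in flu: these 3, AILP1, at least 1.54-fold lower with flu at the floor, and MAMI and XERICO (log2 differences 1.07 and 0.46), the last 3 picked after their values were seen. Over all genes AILP1, MAMI and XERICO did not pass (limma adjusted p = 0.079, 0.071 and 0.060). With the replicate block MAMI and XERICO passed (0.0069 and 0.039), and with the position effect removed they passed at 1.13 and 0.83; no corrected size is given for AILP1, whose flu values are floored.

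In the plastid lists, LPA19, an assembly factor of photosystem II, fell by 1.14 on the log2 scale (SE 0.14) and was the 1 of 7 photosystem, antenna and assembly genes to pass. With the position effect removed it stood at -0.49 (limma adjusted p = 0.024), and it did not pass with a window reaching 6 probe numbers to each side. Of 5 carbon metabolism genes 1 rose, AT5G58330 for the plastid NADP-dependent malate dehydrogenase, by a log2 of 1.40 (SE 0.42, limma adjusted p = 0.042). It did not pass when any flu pair of arrays, or WT arrays 3 and 4, were left out (limma adjusted p from 0.059 to 0.135, with log2 differences from 1.30 to 1.57), nor adjusted over the list alone (0.079). ATSPS4F of the same list had a log2 difference of -0.54 that did not pass (-0.21 with the position effect removed). Of 7 organelle gene expression genes 1 rose, AT5G55580 for the plastid factor mTERF9, by a log2 of 1.25 (SE 0.17), and by 0.79 with the position effect removed. OSB1 and OTP70 had log2 differences of -0.40 and -0.57 that did not pass and were 0.012 and 0.014 with the position effect removed. Of 5 genes for tetrapyrrole and carotenoid enzymes 0 passed; SIRB and Z-ISO had log2 differences of -0.50 and -0.17, or -0.30 and 0.21 with the position effect removed. Of 5 genes for plastid chaperones, translocation and proteases 2 passed: TPP2, a tripeptidyl peptidase, fell by 0.96 on the log2 scale (0.62 with the position effect removed), and Cpn60beta4 was at least 1.42-fold higher in flu, with WT at the floor. The Cpn60beta4 call did not hold with the position effect removed (limma adjusted p = 0.562) or without flu arrays 1 and 2, flu arrays 3 and 4 or WT arrays 5 and 6 (0.061, 0.083 and 0.055), though the position correction acts on floored WT values. Cpn60beta3 had a log2 difference of 0.41 (0.12 with the position effect removed) that did not pass over all genes and did adjusted over the list alone (0.043). SECE1, picked after its values were seen, stood at -0.57 (limma adjusted p = 0.106, and 0.016 with the replicate block; -0.18 with the position effect removed).

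Among 4 calcium-related genes, CML41, a calmodulin-like gene, rose by a log2 of 0.90 (SE 0.17) and passed with the position effect removed. GLR2.7, a glutamate receptor-like gene, fell by 0.62 on the log2 scale and did not pass with the position effect removed, at -0.38 (limma adjusted p = 0.083) or with 5 of the 6 pairs of arrays left out in turn (0.072 to 0.138), and CML30 had a log2 difference of -0.09 that did not pass, but passed at 0.56 with the position effect removed. Of 12 nuclear transcription and chromatin genes 2 rose and 2 fell. LAS, a regulator of axillary meristems, fell by 1.22 on the log2 scale (0.77 with the position effect removed), and IYO, picked after its values were seen, fell by 1.02. DME, a DNA glycosylase that removes methylated cytosine, and SPL, a regulator of sporogenesis, rose by log2 values of 0.78 and 0.91. These 4 passed with the position effect removed, but LAS, DME and SPL did not with the local median by probe number subtracted, and SPL did not with a window reaching 6 or 12 probe numbers to each side, nor without flu arrays 3 and 4 or flu arrays 5 and 6 (limma adjusted p = 0.055 and 0.053, log2 differences 0.87 and 0.81). With the replicate block AGL26, AT4G03090 and chr31, also picked after their values were seen, passed as well (limma adjusted p = 0.025, 0.0497 and 0.045, against 0.091, 0.055 and 0.061), so that 3 rose and 4 fell; their log2 differences were -0.55, -0.62 and 0.51. With the position effect removed AGL26 stood at -0.15, and AT4G03090 and chr31 passed at -0.70 and 0.86.

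What is called the position effect here is a dependence on probe number, seen in the levels of both groups. Whether it arises from position on the arrays is weighed in the last section. Probe number modulo 288 accounted for 33.9% of the variance of the log2 differences, against at most 10.5% in 100 permutations. The period was chosen on these same differences, which favours a high share. The log2 differences of the 3 pairs followed 1 profile over these positions, with correlations of 0.88, 0.91 and 0.88. The mean level depended on position more in WT, with 21.7% of its variance, than in flu, with 13.1%, and permutations reached at most 11.1% in either group. The 189 probes with a number divisible by 6 had a mean log2 difference of 0.47 (SE 0.05), against -0.11 to 0.06 in the other classes modulo 6. AT3G23940, AT2G30100 and CRR41 are among those 189, and each passed with the effect removed. Of the 42 genes named by the rule that passed, 37 also passed in the same direction with the effect removed.

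**Figure D3:**
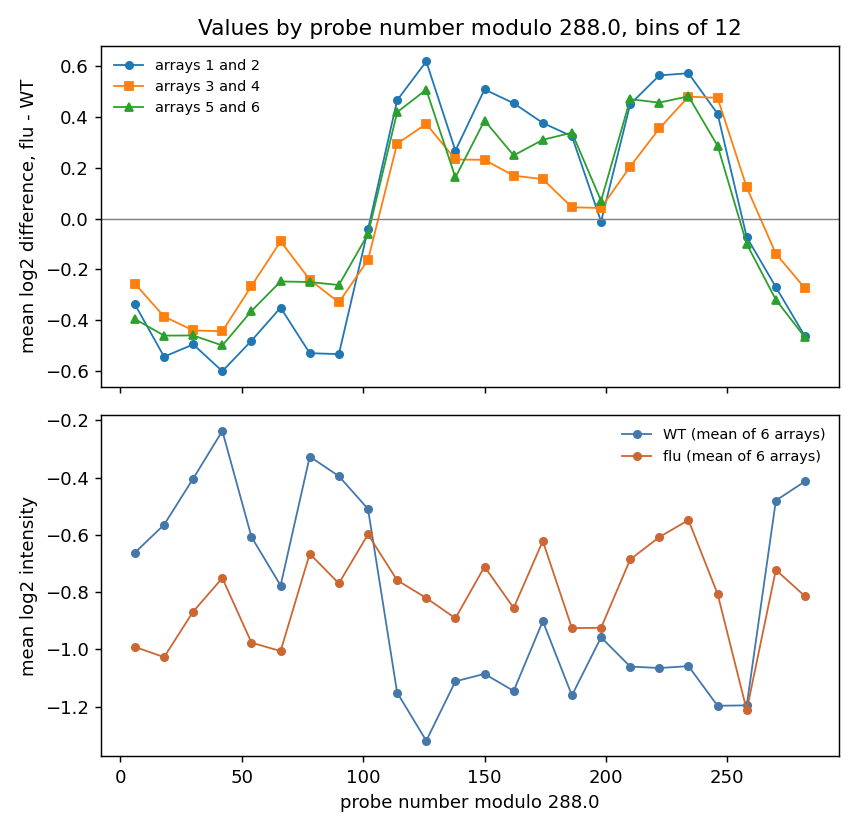
Mean values of the tested probes by probe number modulo 288, in bins of 12 numbers: above, the log2 difference between flu and WT for each of the 3 pairs of arrays, and below, the mean log2 intensity of each group over 6 arrays. The mean difference lies between -0.51 and 0.51 over the bins, and the 3 pairs follow the same profile.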

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

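The 6 arrays of each group were checked for a single array far from the other 5, in 119 groups of values of the named genes and array totals. Of these, 9 had one, and chance flags about 1 group in 20 of independent values without ties. These checks take each array as its own sample. The arrays of a pair resemble each other and values at the floor are tied, so that rate is only a guide. In WT, the intensity of AT2G32470 was 0.414 on array 2, against at most 0.296 on the others (gap over range 0.715). GLDH was 1.04 on WT array 1, against at most 0.954 (0.627), LHB1B2 was 26.9 on WT array 6, against at most 20.6 (0.656), and LPA19 was 0.954 on WT array 6, against at most 0.745 (0.666). CRR41 was 0.916 on flu array 5, against at most 0.768 (0.697). SIRB was 0.402 on flu array 6 and at the floor on the other 5 flu arrays (a ratio of 1). NTRC was 0.322 on flu array 4, against at least 0.417 (0.642), and TPP2 was 0.363 on flu array 4, against at most 0.283 (0.703). WT array 2 had 108 probes at 0, against at least 123 (0.652).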

How the results depend on the processing

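The 12 separate arrays, alone or with the replicate number as a block, were the planned fits. The pair means, the position settings, cyclic loess, the pseudocount of 0.1, the random block, leaving out a whole pair and the local median were chosen after seeing the data; the other alternatives were planned and run on the pair means. The count of probes past the threshold, 1216, lay between 840 and 1371 under every setting that used pair means, with the lowest value without flu arrays 3 and 4. It was 1153 to 1205 without any 1 array, and 1371 with the replicate block, with 1185 of the 1216 in common; among genes named by the rule the block changed the call of PRK only, and among the other list members those of the 6 genes given in the text. With the 12 arrays as separate it was 1732, and with the replicate number as a block on them 1892 (867 higher, 1025 lower); both take the arrays of a pair as independent samples, which the sources used here do not settle. Without a block the 12 arrays also passed PRK, CRR21, NdhS, OSB1, OTP70 and Cpn60beta3, and with it LHB1B2, SBPASE and ATSPS4F too. As deposited, the values put the median log2 difference at -0.12 and 36.9% of the calls higher in flu, against 45.0%. The count of at least 2-fold differences moved from 537 to 51 on log2(value + 1), since most values lie under 1. With the floor at the 10th percentile it was 718, and with the floor at the 40th percentile 368. It was 353 with the position effect removed and 352 with a window reaching 6 probe numbers to each side. By fry 4 of the 11 added lists passed, where camera passed 0.

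Of 42 genes named by the rule that passed, 31 passed in the same direction under every alternative. Beside the losses given in the text, AT5G58330 did not pass with the floor at the 40th percentile, with all probes tested or without WT array 1 or flu array 2; GLR2.7 not with the floor at the 10th percentile, either pseudocount, all probes tested or without WT array 2 or 3 or flu array 2; CSLA01 not with the floor at the 40th percentile; and Cpn60beta4 not with that floor, with the values as deposited or without flu array 5. In the fits without a pair that lost a call, no log2 difference moved by 1.5 times. Leaving out 1 WT pair made SBPASE, CRR21, NdhS, ATSPS4F, SIRB, OSB1, OTP70 and Cpn60beta3 pass, and array weights ATSPS4F and OSB1. AT1G74470 and NdhS passed with the position effect removed and the replicate block. Subtracting the local median by probe number turned the sign of GLR2.7 (0.14), CSLA01 (0.049) and Cpn60beta4 (-0.019). CML30, -0.09 and not past the threshold, became 0.49 there, 0.56 with the position effect removed, also with the replicate block, 0.66 with a window reaching 6 numbers to each side and 0.51 with one reaching 12, past the threshold in each; beyond position, the cause was not tested. Signal over background could not be judged, and dim probes are limited by the floor.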

Other observations

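With the position effect removed, an analysis chosen after seeing the data, 236 of the 620 genes passed, 112 higher and 124 lower in flu. Apart from genes already described, the largest rises were AT4G17070 (log2 1.90, SE 0.46, against 1.51 in the main fit) and AT4G25290 (1.80, SE 0.32, against 1.21), beside AT4G18180, which was at the floor on 5 of 6 WT arrays. The largest falls were AT5G48440 (-1.65, SE 0.27, against -1.15), AT3G44810 (-1.51, SE 0.15, against -0.98) and AT3G08000 (-1.30, SE 0.16, against -1.01), beside AT1G76450, which was at the floor on all flu arrays. IYO, a gene for a protein that associates with RNA polymerase, named above, stood at -1.27 (SE 0.17, against -1.02). All these genes were picked after their values were seen, and by the corrected values, which favours genes whose difference the correction enlarged.

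Of the tests below, those of array position, of the local median, of cyclic loess, of hybridisation batches and of other splits were chosen only after the result was seen. The broad difference between flu and WT took in 1216 probes, only 1 of the 10 splits of the 6 pair means into 3 and 3 gave as many, and the highest other gave 0, among the 3 others that part all same-numbered pair means as well as the 6 that part 1; the others leave the flu and WT difference within their groups, and 10 splits are too few for a share under 0.05. Neither subtracting the local median by probe number, with 1230 probes, nor cyclic loess, with 1232, lowered the count. Cyclic loess shared 1164 of the calls, which argues against a brightness-dependent trend as the whole cause. The local median shared only 798. A median over 49 probes also cannot remove a dependence on probe number modulo 6, so its count does not settle a local trend. Noise of single spots stays open: 78 pairs of probes with identical annotated genes had log2 differences that correlated at 0.11 (two-sided permutation p = 0.319), or 0.024 with the position effect removed, under the 0.2 set beforehand for such noise, but their mean levels correlated at only 0.31, so these pairs may not read the same transcripts. Among the arrays of the other group, each of the 12 arrays deviated most like that of its own number (0.23 to 0.46), which goes against groups handled wholly apart, but batches are not given in the sources used here, so for the component with 61.7% of the variance a hybridisation of flu and WT at separate times stays open, as does the genotype.

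The second pattern is the dependence of the log2 differences on probe number. It is consistent with an effect of position on the arrays, since all 6 contrasts between pair means of the same genotype also depended on probe number modulo 288 beyond the highest of 100 permutations, with shares of variance from 16.8% to 27.6%. A placement of genes by expression level would make mean log2 intensity depend on position too. Position took 15.1% of its variance and 21.7% in WT, above the permutations (at most 11.1%) but under the 33.9% for the differences. Each share is of a different total variance, so the lower shares cannot decide against level. Over bins of probe number modulo 288, the mean WT level ran from -1.32 to -0.24 and the mean difference from -0.51 to 0.51. Placement by level therefore stays open. The correlation of log2 differences between probes 288 numbers apart was 0.31, and 0.10 with the effect removed, so a part remains. Placement by function was not tested, and no layout of the arrays was used here.

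The third pattern is how many calls this effect may account for. With it removed, 65.1% of the 1216 called probes passed in the same direction, between the bounds of 50% and 80% set for a main or a minor part, and 25 changed the sign of their estimate. The log2 differences kept 76.8% of their variance. Position may therefore account for part of the calls, and which of the lost calls were due to it cannot be told apart, because in data simulated with such an effect the fit without the correction made 682.6 false calls, against 7.4 with it, but the corrected fit also recovered fewer of the changed probes, 60.8% against 76.3%. The simulated effect was of the kind the correction is built to remove. In the real data position still took 14.0% of the variance of the corrected differences, against at most 10.2% in permutations. The 7.4 may therefore be too low for them.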
